A study of Mus musculus with 16 samples.

How the data were processed

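Gene expression was measured in total RNA from mouse quadriceps muscle, 100 ng per sample, labelled with biotin and hybridised to Illumina bead arrays, per the labels' protocols. The 16 arrays fall into 4 groups of 4 by the genotype and treatment in their labels, and every column of the deposited tables matched 1 sample. The arrays came from 2 chips of 8.

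The deposited non-normalized table gives, per the file headers, an intensity for each of 25697 probes on each array and a detection p-value from the scanner software. Between 6907 and 7499 intensities per array lie below 0, so the background had been subtracted before deposit; how is not given in the sources used here. In 2 columns 60 cells were not numbers (14 in WT replicate 1 and 46 in ASO 190401 replicate 4, touching 18 of the genes tested) and were treated as missing. The authors' deposited processed matrix holds intensity values on a linear scale with array medians of 26.4 to 26.5 and a floor between 2 and 2.4. Its arrays share nearly the same quartiles, its genes are not centred, and its ranks follow the non-normalized values above an intensity of 100, so its scale and direction are settled; its background treatment is not. The submitters' processing notes name the tool affy, with no version and no role. The matrix was used as an alternative.

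Genes were named through GEO's platform annotation, which pairs 23978 probes with 1 gene, 0 with several and leaves 1719 unnamed here. Of these symbols 0 changed when looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, in which 23962 probes matched. No coordinates are given, since the array names no genome build.

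In R 4.3.3 with limma 3.58.1, intensities were corrected by normexp with background parameters estimated from the detection p-values and an offset of 16, quantile normalized over the 16 arrays and put on the log2 scale. Probes with a detection p under 0.05 on at least 4 arrays were kept (12364, of which 684 unnamed). Each gene was represented by its probe with the highest mean, leaving 8725 genes, of which 2188 had several probes. One linear model with a mean per group (12 residual degrees of freedom) gave 6 comparisons by two-sided moderated tests with an intensity trend, with Benjamini-Hochberg adjustment at 0.05 within each comparison. Where the probe of a gene was below background on all 4 arrays of a group, the fold is given as at least N-fold. This is the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes above background and the gene's own.

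The choice of tests, alternatives, gene lists and the rule for naming genes was made before the data were examined, except for those tests of explanations that the closing section names as chosen later. The rule names, per comparison, the 12 genes with the largest positive and the 12 with the largest negative difference among called genes whose 4 arrays of one group all lie above the 4 of the other (6 and 6 between the oligos). It adds up to 4 called members of each list (or 2 with the smallest p where none is called) and always Acta1, Clcn1, Mbnl1, Mbnl2 and Rnaseh1. The text gives a part of these.

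The 28 lists were slow fibre, fast fibre, extracellular matrix, regeneration and denervation, excitation with calcium and ion channels, RNA-binding proteins of splicing, actins, RNase H, oxidative phosphorylation and TCA cycle, fatty acid use, glycolysis and glycogen, interferon response, immediate early genes, heat shock, atrophy and proteasome, unfolded protein and integrated stress response, p53 targets, circadian clock and ribosomal proteins, with markers of myeloid cells, lymphocytes, adipocytes, endothelial cells, fibroblasts, smooth muscle and pericytes, erythroid cells, nerve and Schwann cells, and satellite cells. Of 415 members 301 were measured. Lists were tested with limma's camera (preset correlation of 0.01, and again with an estimated correlation) and fry, adjusted over the lists of a comparison. Camera compares a list with all other genes, while fry tests whether its genes move on balance one way and its mixed p whether they change in either direction. The median, mean and camera direction differed in sign in 16 of 162 pairs of list and comparison, of which 0 were called.

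Return toward WT is the percent of each gene's HSALR saline minus WT difference undone under an oligo, and its median was recomputed with the saline arrays split between the differences (6 ordered splits). Correlation of the oligo effects was set against 100 simulations of unchanged groups sharing the saline arrays. The fit was tested on simulated data. For ASO 445236 minus saline over 8725 genes it called 6 of 50 genes changed 1.2-fold, 29 of 50 changed 1.5-fold, 45 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 9 false calls. A simulated return of 40% was estimated at 39.8% and one of 0% at 1.80%.

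Correlations between arrays of a group ran from 0.9785 to 0.9921, and 0 pairs were identical. Alternatives were raw intensity without background correction, median scaling, the authors' deposited values, a stricter filter and none, no intensity trend, array weights, the 8 arrays compared alone, chip position as a covariate, each probe tested, the mean of a gene's probes, a minimum of 2-fold, a test against 1.2-fold, other set tests, and leaving out each array in turn. Chip was not a term of the model, since each group lies on 1 chip, and the comparisons within a chip do not change with it.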

Results

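Total RNA from the quadriceps muscle of adult FVB/n mice was profiled on 16 Illumina bead arrays in 4 groups of 4. The groups were wild-type (WT) mice given saline, and HSALR mice given saline, antisense oligo (ASO) 445236 or ASO 190401. HSALR mice carry a human skeletal actin transgene with a long CUG repeat and serve as a model of myotonic dystrophy, in which repeat RNA is held in the nucleus. Injections were subcutaneous and lasted 4 weeks. Between 10835 and 11700 of the 25697 probes lay above background on each array, and the number of arrays limits the precision. The labels name separate samples but do not say that each came from its own animal, so p-values measure the spread between these arrays. The HSALR saline and ASO 445236 arrays shared 1 chip, and the WT and ASO 190401 arrays shared the other. ASO 445236 against saline and ASO 190401 against WT were therefore the 2 comparisons made within a chip, and in the other 4 chip and group cannot be told apart. Below, a gene is called at a limma adjusted p under 0.05 among 8725 genes tested, values after ± are standard errors of log2 differences unless marked SD, and each group has n = 4.

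The first principal component held 32.3% of the variance and parted the saline groups, at -24.3 ± 4.79 (SD, n = 4) for WT and 22.0 ± 2.51 (SD, n = 4) for HSALR. ASO 445236 lay between them at -0.85 ± 5.57 (SD, n = 4) and ASO 190401 at 3.14 ± 0.82 (SD, n = 4). The second held 13.2% and parted both oligo groups, at 10.2 and 9.60, from both saline groups, each at -9.92.

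**Figure D1:**
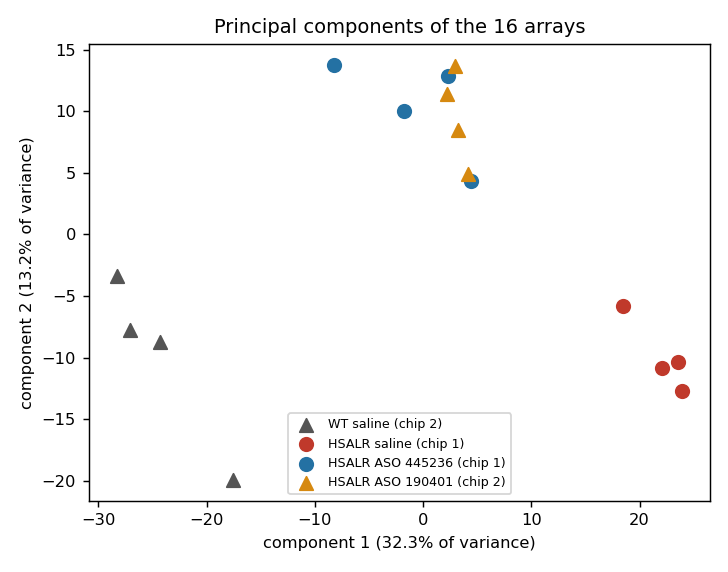
Principal components 1 and 2 (arbitrary units, with the percent of variance each holds) of the log2 intensities of the 16 arrays; each point is an array, coloured by group and shaped by chip. Both oligo groups lie between WT saline and HSALR saline on component 1 and above both on component 2.

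HSALR saline against WT saline asks how the transgene changes muscle gene expression. Mouse Acta1, the homolog of the transgene's coding part, did not pass the test (-0.073 ± 0.059, adjusted p = 0.39), and since probe sequences were not used here, whether its probe also detects the human transgene is not known. In HSALR muscle 1228 genes rose and 1146 fell, with 218 and 105 of them at least 2-fold. The largest rises were in Pcdhb12, a protocadherin, at least 282-fold, and Cacna2d3, an auxiliary subunit of calcium channels, at 7.93 ± 0.26. Ramp3, which modifies receptors of the calcitonin family, rose at least 19.7-fold, and Sln, which encodes the calcium pump inhibitor sarcolipin, by 4.33 ± 0.44 (3.64 without WT replicate 1). Kcnab1, a potassium channel subunit, fell by 3.85 on the log2 scale (SE 0.18) and Actc1, cardiac actin, fell by 3.58 (SE 0.23). Cacna2d3 was above background on 2 of the 4 WT arrays and Pcdhb12 and Ramp3 on 0. Pdlim2 rose at least 48.3-fold by its brightest probe, while its 2 other probes went the opposite way.

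Genes of muscle regeneration and denervation rose together, with 9 of 14 measured higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.000242, and adjusted p = 0.32 with an estimated correlation). They included Sln, the perinatal myosin Myh8 at 1.70 ± 0.26 and the cell cycle inhibitor Cdkn1a at 1.58 ± 0.15, while Actc1 was the member that fell. Of 10 immediate early genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0126, and adjusted p = 0.32 with an estimated correlation), with the stress-induced transcription factor Atf3 at 2.67 ± 0.29 and Fosb, above background on 1 of the 4 WT arrays, at 1.58 ± 0.37. Of 8 p53 targets 3 rose, among them Phlda3 at 1.73 ± 0.14 (3 adjusted over the list alone; camera adjusted p = 0.0548). Fry, which tests whether the genes of a list move on balance one way, gave these an adjusted p of 0.000262. The small heat shock protein gene Hspb7 rose by 1.96 ± 0.18, and the neurotrophin receptor gene Ngfr, above background on 3 of the 4 WT arrays, by 3.09 ± 0.25.

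Of 21 genes of excitation and calcium handling 10 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.0624, fry adjusted p = 0.000511). The calcium channel subunit gene Cacng1 rose by 0.69 ± 0.12 and the potassium channel gene Kcna7 by 0.68 ± 0.16, while Casq1, the calcium store protein of fast fibres, was lower at -0.59 ± 0.13. Clcn1, the muscle chloride channel whose loss causes myotonia, was lower at -0.48 ± 0.15 (adjusted p = 0.026) by its brighter probe alone. Among RNA-binding proteins of splicing 2 of 16 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.413, fry adjusted p = 0.0151). Celf2 was lower at -0.99 ± 0.066 and Hnrnph1 at -1.23 ± 0.14, Celf1 was higher at 0.42 ± 0.11, and Mbnl1 (0.054 ± 0.093, adjusted p = 0.71) and Mbnl2 (-0.14 ± 0.086, adjusted p = 0.25) were not called. The Clcn1 call was lost with chip position as a covariate (adjusted p = 0.0518), with the mean of its 2 probes (0.0646) and when HSALR saline replicate 1 (0.0826) or 3 (0.0679) or WT replicate 2 (0.0618), 3 (0.0866) or 4 (0.0524) was left out; its alternatives ran from 0.00657 to 0.0866.

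Interferon response genes were lower, with 12 of 15 down and 0 up (13 down adjusted over the list alone; camera adjusted p = 6.03e-06, and adjusted p = 0.32 with an estimated correlation). Ifi27l2a stood at -1.60 ± 0.24, Usp18, which limits interferon signalling, at -1.22 ± 0.16, and Gbp3 at -0.93 ± 0.19. Fibroblast markers fell in 5 of 9 cases (7 adjusted over the list alone; camera adjusted p = 0.000543, and adjusted p = 0.32 with an estimated correlation), with Pi16 at -1.20 ± 0.18 and Dpt at -1.01 ± 0.19. Extracellular matrix genes fell in 6 of 20 cases and rose in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0222, and adjusted p = 0.612 with an estimated correlation), with the basement membrane gene Nid1 at -0.86 ± 0.11, Dcn at -0.58 ± 0.061 and the protease inhibitor gene Timp1 higher at 0.91 ± 0.19. That call was lost without WT replicate 1 (adjusted p = 0.135) or 2 (0.0502) or HSALR saline replicate 3 (0.0585). Fatty acid use genes fell in 8 of 16 cases (10 adjusted over the list alone; camera adjusted p = 0.000871, and adjusted p = 0.358 with an estimated correlation), among them Eci1, an enzyme of fatty acid oxidation, at -0.49 ± 0.088. Slow fibre genes, measured beside them, had a median of -1.60, with 1 of 12 lower and 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 0.0905), and 0 lower without HSALR saline replicate 2 or 4 or WT replicate 3 or 4. Markers of myeloid cells (median -0.43, 1 of 15 higher and 1 lower, camera adjusted p = 0.0624) and adipocytes (median -0.85, 3 of 9 lower, camera adjusted p = 0.0624) were not called as lists. Without WT replicate 1, 8 myeloid markers were lower, and without HSALR saline replicate 3 or WT replicate 3, 0 adipocyte markers were.

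ASO 445236 against saline in HSALR mice asks what this oligo changed, and both groups were on the same chip. Acta1 was not called (0.054 ± 0.059, adjusted p = 0.61), and 595 genes rose while 589 fell, 70 and 95 of them at least 2-fold. Under median scaling the split was 1529 higher and 257 lower, since the median of all genes then shifted by 0.161. The raw 75th percentile of intensity was lowest in HSALR saline, at 112 ± 7.63 (SD, n = 4). It was 139 ± 11.9 in WT, 146 ± 8.91 under ASO 445236 and 163 ± 22.9 under ASO 190401 (SD, n = 4 each), and the cause was not tested. The largest rises were in Wfdc17 at 3.80 ± 0.31, the chemokine gene Ccl8 at least 7.67-fold, and Ms4a7, a membrane protein gene of macrophages, at 2.57 ± 0.30. Wfdc17 was above background on 2 of the 4 saline arrays and Ms4a7 on 3. The other probe of Ms4a7 differed by 0.523. Ramp3 was lower at -4.91 ± 0.28 and Idi2, an isomerase of the isoprenoid pathway, at -3.40 ± 0.23, but under ASO 445236 these were above background on 1 and 2 of the 4 arrays. Actc1 rose by 2.44 ± 0.23 and Kcnab1 by 1.95 ± 0.18.

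Myeloid markers rose in 10 of 15 cases under ASO 445236 and fell in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 2.86e-08, and adjusted p = 0.693 with an estimated correlation). Adgre1, the macrophage F4/80 antigen, above background on 3 of the 4 saline arrays, rose by 1.99 ± 0.31, and the lysozyme gene Lyz2 by 1.93 ± 0.33. Interferon response genes rose in 9 of 15 cases (10 adjusted over the list alone; camera adjusted p = 2.78e-07, and adjusted p = 0.53 with an estimated correlation), with Ifi27l2a at 1.78 ± 0.24, Oasl2 at 1.46 ± 0.20 and Usp18 at 1.27 ± 0.16, beside the myeloid rise. Fatty acid use genes rose in 4 of 16 cases (4 adjusted over the list alone; camera adjusted p = 0.009, and adjusted p = 0.693 with an estimated correlation). Beside them 3 of 9 adipocyte markers rose (4 adjusted over the list alone; camera adjusted p = 0.0485, and adjusted p = 0.693 with an estimated correlation), with the adipokine gene Lep at 1.27 ± 0.27. Endothelial markers fell in 1 of 11 cases (4 adjusted over the list alone; camera adjusted p = 0.009, and adjusted p = 0.693 with an estimated correlation), the member being Flt1 at -0.76 ± 0.22. Clcn1 rose by 0.74 ± 0.15 (adjusted p = 0.0031) by its brighter probe, while its other probe differed by 0.0285. Usp18 also had another probe, which differed by 0.673. Celf2 rose by 1.03 ± 0.066 and Hnrnph1 by 0.73 ± 0.14. Ngfr was lower at -2.41 ± 0.25, Hspb7 at -1.72 ± 0.18, Phlda3 at -1.40 ± 0.14 and the Z-disc protein gene Csrp3 at -1.52 ± 0.26. The fatty acid call was lost without ASO 445236 replicate 4 (adjusted p = 0.0567) or saline replicate 1 (0.0595), and the endothelial call without ASO 445236 replicate 1 (0.0947). The adipocyte call was lost without ASO 445236 replicate 1 (0.308), saline replicate 2 (0.0641) or 3 (0.164), with median scaling (0.142) and with the authors' deposited values (0.0747). The Flt1 call was lost with median scaling (0.0616) and without ASO 445236 replicate 1 (0.075), 3 (0.0772) or 4 (0.0757) or saline replicate 3 (0.0743) or 4 (0.0565), its alternatives running up to 0.0772. By fry, fatty acid use (adjusted p = 0.0636), adipocytes (0.189) and endothelial cells (0.13) were not called. Actins (fry adjusted p = 0.024), satellite cells (0.024) and p53 targets (0.028) were called by fry alone.

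ASO 190401 against saline in HSALR mice asks the same of the other oligo, across chips. Acta1 was not called (-0.093 ± 0.059, adjusted p = 0.32), and 705 genes rose while 671 fell, 34 and 89 of them at least 2-fold. Median scaling shifted the median of all genes by 0.18 and gave 1938 higher and 296 lower. F2rl3, a protease-activated receptor gene above background on 1 of the 4 saline arrays, rose by 1.67 ± 0.16 and Kcnab1 by 1.62 ± 0.18. Ms4a7 rose by 1.41 ± 0.30 (adjusted p = 0.0035), and its other probe differed by 0.235. Mup2, a major urinary protein gene, rose by 4.25 ± 1.0; it was above background on 1 of the 4 saline arrays, replicate 1, and without that array the rise was at least 26.4-fold. Ramp3, above background on 3 of the 4 ASO 190401 arrays, was lower at -3.82 ± 0.28, Idi2 at -2.53 ± 0.23, Ngfr at -2.05 ± 0.25, Irf5, an interferon regulatory factor gene, at -2.00 ± 0.15, and Hspb7 at -1.75 ± 0.18.

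Extracellular matrix genes fell in 11 of 20 cases under ASO 190401 and rose in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 7.11e-06, and adjusted p = 0.557 with an estimated correlation), with the collagen genes Col3a1 at -1.36 ± 0.26, Col1a1 at -1.26 ± 0.29 and Col6a2 at -1.14 ± 0.20. Fibroblast markers, measured beside them, had a median of -0.18 with 0 of 9 called (camera adjusted p = 0.702). Interferon response genes rose in 7 of 15 cases (7 adjusted over the list alone; camera adjusted p = 2.58e-05, and adjusted p = 0.557 with an estimated correlation), with Oasl2 at 1.65 ± 0.20, Usp18 at 1.46 ± 0.16 and Ifit3 at 1.32 ± 0.19. Myeloid markers had a median of 0.32 beside that rise, with 1 of 15 higher (0 adjusted over the list alone; camera adjusted p = 0.366), and 0 higher without saline replicate 1, 2 or 3 or ASO 190401 replicate 2 or 3. Clcn1 rose by 0.78 ± 0.15 (adjusted p = 0.0021) by its brighter probe, while its other probe differed by 0.236. Usp18 also had another probe, which differed by 0.461. Celf2 rose by 0.86 ± 0.066, Hnrnph1 by 0.68 ± 0.14 and Rbfox1, a splicing factor gene, by 0.39 ± 0.093. Mbnl2 rose by 0.30 ± 0.086 (adjusted p = 0.024), a call lost without the intensity trend (0.06) and without saline replicate 2 (0.0744), 3 (0.0556) or 4 (0.0536) or ASO 190401 replicate 2 (0.077) or 4 (0.0968), with alternatives from 0.00247 to 0.0968. Nerve and Schwann cell markers were lower by fry alone (adjusted p = 0.0211, camera adjusted p = 0.183).

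**Figure D2:**
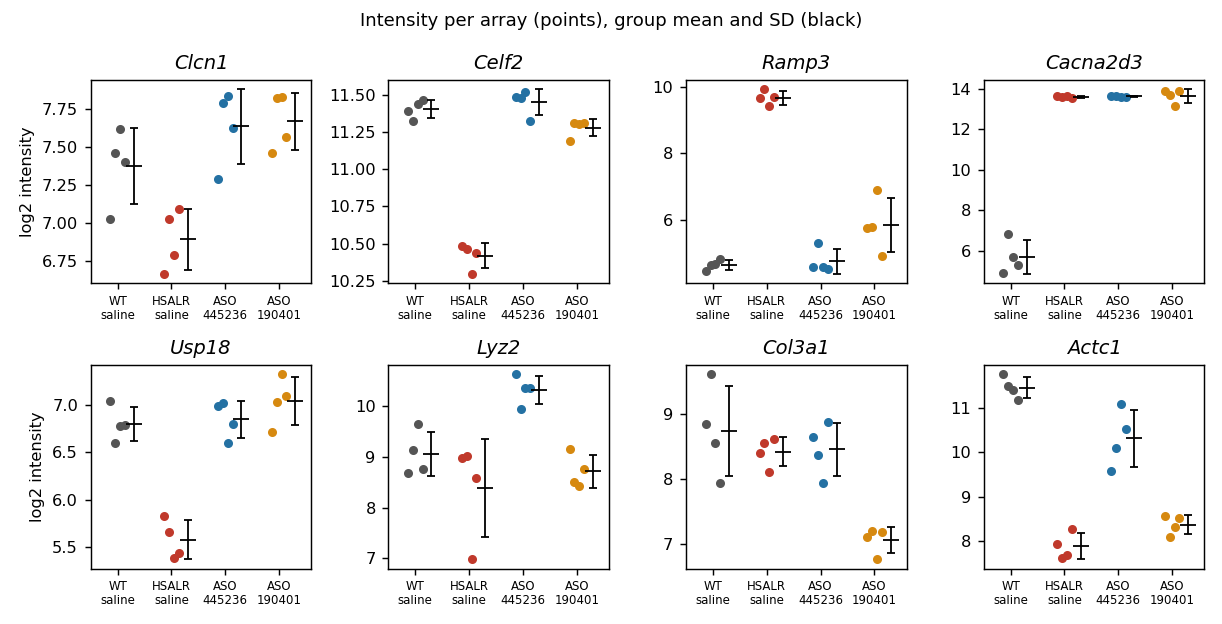
Log2 intensity of 8 named genes on each of the 16 arrays (points, coloured by group), with the group mean and SD in black (n = 4 each); each panel has its own vertical scale. Cacna2d3 stays high in all HSALR groups, Ramp3 is lower under both oligos than under saline, Lyz2 is highest under ASO 445236 and Col3a1 lowest under ASO 190401.

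The next comparison asks how far each oligo moved the 2374 genes called between the saline groups back toward WT. Under ASO 445236 2150 of them (90.56%) moved opposite to the HSALR difference, 838 of these past the threshold against 6 called in the same direction. The median return was 53.75%, where 100% is the WT level, and fry gave a limma p of 3.025e-09. Under ASO 190401 2117 (89.17%) moved opposite, 950 called against 15, with a median return of 57.47% (p of 3.019e-09 by limma's fry). Both differences use the saline arrays, which by itself gives some return. With the 4 saline arrays split between them, the median ran from 42.22% to 50.74% for ASO 445236 and from 46.41% to 54.19% for ASO 190401 over 6 splits, and fry's limma p was at most 1.364e-06 and 1.508e-06. HSALR saline lay on the other chip from WT and ASO 190401. An offset between chips would thus count as return under ASO 190401, and the splits do not remove it. The returns under the oligos are therefore not measured alike. An index per array over 2367 genes, 0 for WT and 100 for HSALR saline, was 51.2 ± 8.19 (SD, n = 4) under ASO 445236 and 56.7 ± 1.60 (SD, n = 4) under ASO 190401 (exact two-sided permutation p = 0.314, smallest possible 0.0286). The index weights each gene by its squared HSALR saline minus WT difference, so the largest differences count most. Over the 2323 genes that differed by less than 4-fold it was 44.6 ± 9.45 and 48.7 ± 1.86 (SD, n = 4 each, exact two-sided permutation p = 0.514).

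F2rl3, above background on 1 saline array, returned by 78.0% under ASO 445236 and 89.1% under ASO 190401, and Kcnab1 by 50.8% and 42.1%. By the probes tested, Ramp3, Idi2 and Pcdhb12 were below background on every WT array, so no percent is given for them. Pcdhb12 was lower under both oligos than under saline, at -1.29 (adjusted p = 7.9e-06) and -0.794 (adjusted p = 0.001). Other genes returned by little, and Cacna2d3 (-0.253% and -0.506%), Atrip (3.43% and 3.24%), a DNA damage checkpoint gene, and Chic2 (2.73% and 3.91%) were called under neither oligo. Ntrk2, another neurotrophin receptor gene, returned by 73.5% under ASO 445236 and 5.29% under ASO 190401, where it was not called; the test of that difference gave an adjusted p of 0.00685. Actc1 returned by 68.1% and 13.8%, not called under ASO 190401, with an adjusted p of 0.00016 for the difference. Both tests are between the oligos and so across chips. Of the 12 interferon genes called between the saline groups, 9 were called back under ASO 445236, 7 under ASO 190401 and 6 under both. Of 10 regeneration genes 4, 1 and 1 were called back, of 13 excitation genes 4, 2 and 2, and of 4 heat shock genes 2, 4 and 2. For scale, 838, 950 and 583 of all 2374 genes were called back.

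**Figure D3:**
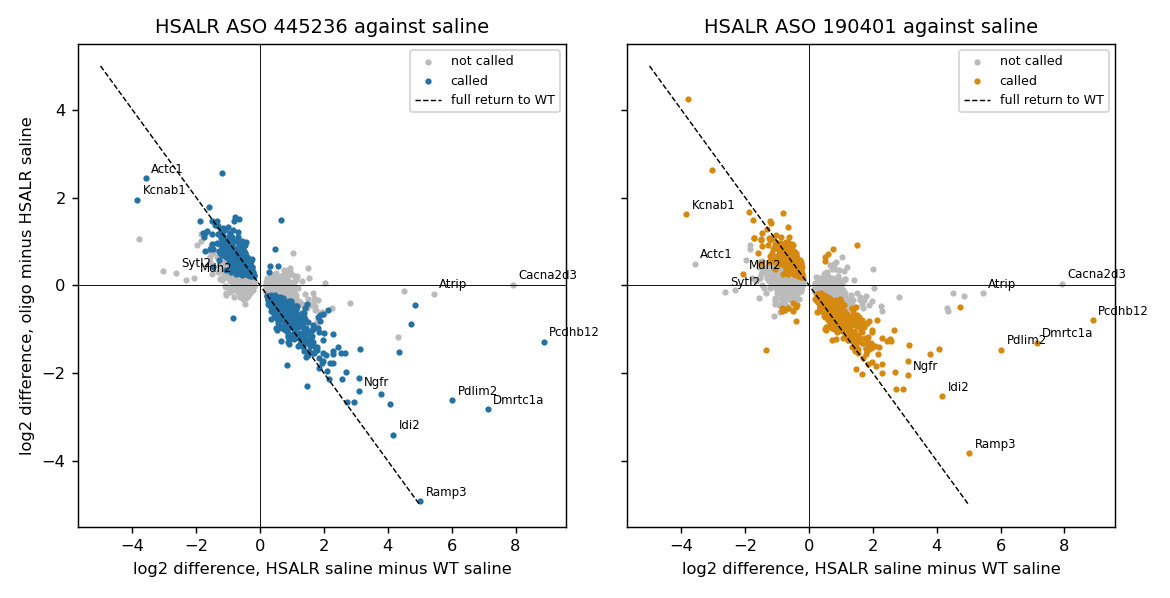
Log2 difference of oligo minus HSALR saline (vertical) against HSALR saline minus WT saline (horizontal) for the 2374 genes called between the saline groups, ASO 445236 left and ASO 190401 right; coloured points are genes also called for the oligo. Points on the dashed line returned fully to the WT level, and the median return was 53.75% and 57.47%. An offset between chips would count as return on the right.

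Each oligo group was also set against WT saline, which asks what still differed. ASO 190401 and WT shared a chip, and 444 genes were higher and 461 lower, 74 and 80 of them at least 2-fold. Median scaling, with a shift of 0.183, gave 1808 higher and 282 lower, and a fit on the 8 arrays alone called 589. Pcdhb12 stayed at least 163-fold higher, Cacna2d3 was higher by 7.97 ± 0.26, Sln by 3.82 ± 0.44 (3.13 without WT replicate 1) and Chrng, the fetal acetylcholine receptor subunit, above background on 1 of the 4 WT arrays, by 2.41 ± 0.26. Actc1 was lower at -3.09 ± 0.23. Extracellular matrix genes were lower in 14 of 20 cases and higher in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 4.29e-15, and adjusted p = 0.0296 with an estimated correlation), with Col3a1 at -1.67 ± 0.26 and Col6a2 at -1.57 ± 0.20. Regeneration genes were higher in 9 of 14 cases and lower in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 3.9e-08, and adjusted p = 0.0475 with an estimated correlation). Actins were lower in 2 of 4 cases, Actc1 and Acta2 at -0.99 ± 0.23 (3 adjusted over the list alone; camera adjusted p = 0.000153, and adjusted p = 0.0296 with an estimated correlation). These 3 were the camera calls, of 37 over all lists and comparisons, that held with an estimated correlation.

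Markers of 4 other cell types were lower beside the matrix genes under ASO 190401 than in WT. Myeloid markers (median -0.344, 1 of 15 higher and 1 lower, camera adjusted p = 0.233) were not called as a list, nor by camera were smooth muscle (0.13), nerve (0.206) or satellite cell markers (0.662). Fibroblast markers were lower in 7 of 9 cases (9 adjusted over the list alone; camera adjusted p = 2.08e-08, and adjusted p = 0.0902 with an estimated correlation), with Mfap5 at -1.17 ± 0.17. Adipocyte markers were lower in 4 of 9 cases (7 adjusted over the list alone; camera adjusted p = 3.97e-05, and adjusted p = 0.278 with an estimated correlation), with Lep at -1.26 ± 0.27. Endothelial markers were lower in 4 of 11 cases (8 adjusted over the list alone; camera adjusted p = 4.07e-05, and adjusted p = 0.278 with an estimated correlation), with Ramp2 at -0.66 ± 0.12. Erythroid markers were lower in 1 of 4 cases (4 adjusted over the list alone; camera adjusted p = 0.00505, and adjusted p = 0.278 with an estimated correlation). The member was the haemoglobin gene Hbb-bt at -2.04 ± 0.53, whose call was lost without WT replicate 2 (-1.41, adjusted p = 0.054) or 3 (0.0504) or ASO 190401 replicate 2 (0.0543), with alternatives from 0.00432 to 0.0543. The slow fibre list was lower with 0 of 12 members called (0 adjusted over the list alone; camera adjusted p = 0.00405, and adjusted p = 0.56 with an estimated correlation), a call lost without ASO 190401 replicate 1 (0.0742) or WT replicate 2 (0.0736). Fatty acid use genes were lower in 4 of 16 cases (5 adjusted over the list alone; camera adjusted p = 0.0006, and adjusted p = 0.278 with an estimated correlation), but under median scaling the list's median turned from -0.202 to 0.0513 (camera adjusted p = 0.128). Of 8 p53 targets 2 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.00881, and adjusted p = 0.214 with an estimated correlation). The slow fibre list was not called by fry (adjusted p = 0.278). Excitation, oxidative phosphorylation and clock genes (each at a fry adjusted p of 0.00759) and nerve markers (0.0485) were called by fry alone.

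Under ASO 445236, 549 genes were higher than in WT and 441 lower, 83 and 31 of them at least 2-fold, across chips. Median scaling, with a shift of 0.149, gave 1455 higher and 164 lower, a fit on the 8 arrays alone called 471, and leaving out ASO 445236 replicate 3 called 541. Cacna2d3 was higher by 7.95 ± 0.26, Pcdhb12 at least 116-fold, Wfdc17, above background on 3 of the 4 WT arrays, by 3.09 ± 0.31, Ccl8, above background on 1 of them, by 3.09 ± 0.29 and Lgals3, the galectin gene of macrophages, by 2.15 ± 0.18. Myeloid markers were higher in 6 of 15 cases (6 adjusted over the list alone; camera adjusted p = 0.000897, and adjusted p = 0.53 with an estimated correlation). Regeneration genes were higher in 7 of 14 cases and lower in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 9.48e-05, and adjusted p = 0.344 with an estimated correlation), with Chrng at 1.89 ± 0.26. Excitation genes were higher in 6 of 21 cases and lower in 1 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0077, and adjusted p = 0.29 with an estimated correlation). Clcn1 was not called against WT under ASO 445236 (0.26 ± 0.15, adjusted p = 0.31, its other probe going the opposite way) or ASO 190401 (0.29 ± 0.15, adjusted p = 0.25). Extracellular matrix genes were lower in 6 of 20 cases and higher in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 8.65e-05, and adjusted p = 0.372 with an estimated correlation). Beside them endothelial markers were lower in 6 of 11 cases (8 adjusted over the list alone; camera adjusted p = 1.13e-05, and adjusted p = 0.372 with an estimated correlation). Fibroblast markers were lower in 2 of 9 cases (3 adjusted over the list alone; camera adjusted p = 0.00803, and adjusted p = 0.492 with an estimated correlation). Slow fibre genes were lower in 1 of 12 (1 adjusted over the list alone; camera adjusted p = 0.0174, and adjusted p = 0.644 with an estimated correlation). The fibroblast call was lost without ASO 445236 replicate 2 (0.0592) and the slow fibre call without WT replicate 2 (0.14). The number of members called fell to 0 without ASO 445236 replicate 2 or 3 or WT replicate 2 in both lists, and without WT replicate 3 in fibroblasts. Fry called neither slow fibre genes (adjusted p = 0.319) nor myeloid or fibroblast markers (0.0788 each). It alone called actins (fry adjusted p = 0.015), oxidative phosphorylation (0.0259), satellite cells (0.0432) and p53 targets (0.0346).

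The oligos were then compared with each other, across chips, which tests the difference of their effects together with any difference between chips. Of the genes tested 171 were higher and 95 lower under ASO 445236 than under ASO 190401, 45 and 13 of them at least 2-fold. Wfdc17 was higher by 2.64 ± 0.31, Actc1 by 1.94 ± 0.23, Lep by 1.68 ± 0.27 and Col3a1 by 1.39 ± 0.26. Socs2, a suppressor of growth hormone signalling, was lower at -1.91 ± 0.23, Ankrd1 at -1.31 ± 0.18 and Cdkn1a at -0.94 ± 0.15. Clcn1 differed by -0.034 ± 0.15 (adjusted p = 0.94). Myeloid markers were higher in 8 of 15 cases (11 adjusted over the list alone; camera adjusted p = 1.38e-09, and adjusted p = 0.355 with an estimated correlation). Extracellular matrix genes were higher in 6 of 20 (11 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.53e-08, and adjusted p = 0.194 with an estimated correlation). Adipocyte markers were higher in 2 of 9 cases (6 adjusted over the list alone; camera adjusted p = 2.79e-06, and adjusted p = 0.355 with an estimated correlation). Fibroblast markers were higher in 3 of 9 (5 adjusted over the list alone; camera adjusted p = 0.000164, and adjusted p = 0.355 with an estimated correlation) and actins in 1 of 4, Actc1 (2 adjusted over the list alone; camera adjusted p = 0.00502, and adjusted p = 0.194 with an estimated correlation). Erythroid markers were higher with 0 of 4 called (2 adjusted over the list alone; camera adjusted p = 0.0216, and adjusted p = 0.584 with an estimated correlation). Heat shock genes were lower with 0 of 8 called (2 adjusted over the list alone; camera adjusted p = 0.0216, and adjusted p = 0.457 with an estimated correlation). The fibroblast markers called fell to 0 without ASO 445236 replicate 1 or 4 or ASO 190401 replicate 1, and the myeloid markers called to 2 without ASO 445236 replicate 4 or ASO 190401 replicate 2. The erythroid call was lost without ASO 445236 replicate 1 (0.205) or 2 (0.0688), and the heat shock call without ASO 190401 replicate 2 (0.156) or ASO 445236 replicate 3 (0.0536). Between the oligos fry did not call myeloid cells (adjusted p = 0.0716), erythroid cells (0.264) or adipocytes, fibroblasts and heat shock (0.0896 each). The count of 266 genes fell to 110 without ASO 445236 replicate 4, 175 without its replicate 3, 119 without ASO 190401 replicate 2 and 127 without its replicate 4, and rose to 526 with array weights.

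**Figure D4:**
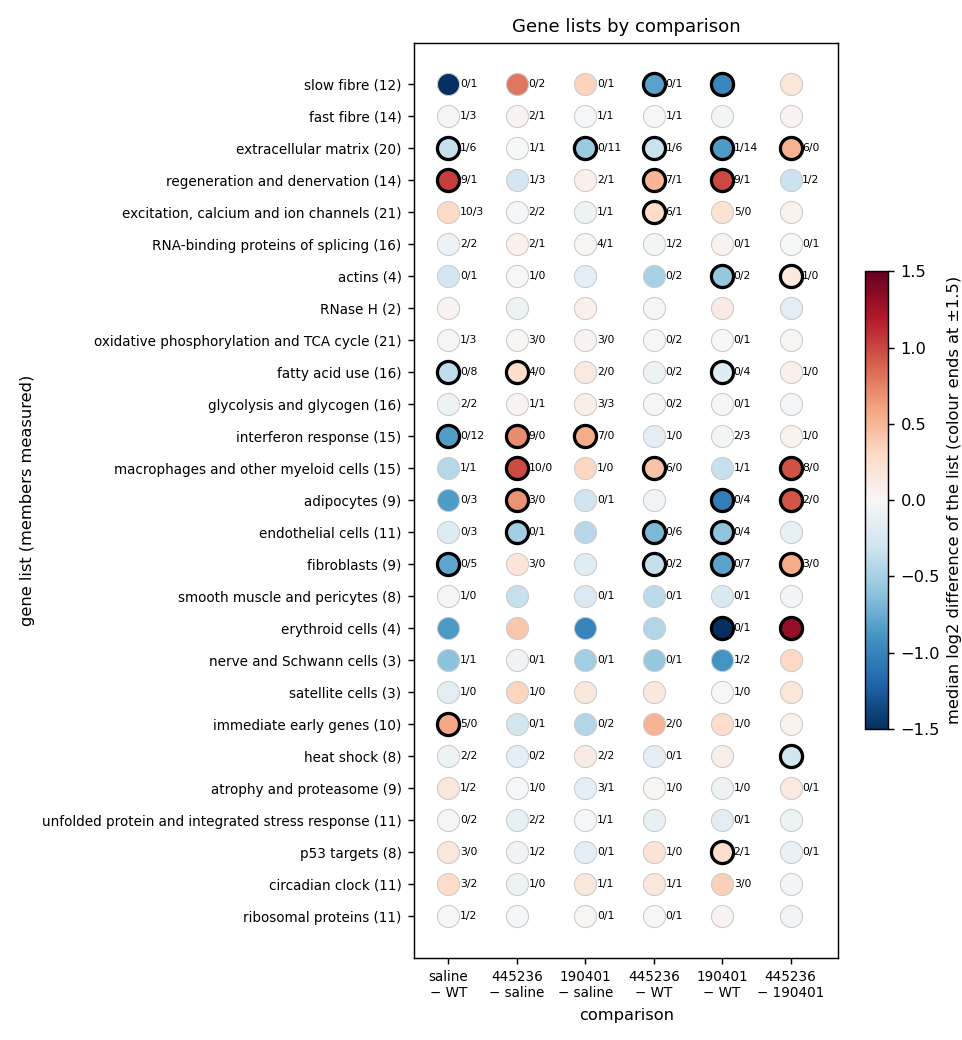
Gene lists (rows of dots, with the number of members measured) by comparison (columns); the colour is the median log2 difference, a thick outline marks a camera adjusted p under 0.05, and the figures beside a dot count members called higher and lower. Interferon genes are lower in HSALR saline than in WT and higher under both oligos than under saline.

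Across the 8725 genes, which are not independent replicates, the effects of the oligos against saline correlated at r = 0.682. Unchanged groups simulated against the shared saline arrays gave 0.465 on average (from -0.456 to 0.951), and splitting the saline arrays gave 0.4625 to 0.5699. The covariance was 0.0842 against a simulated 0.0155 (from -0.00726 to 0.0595), a difference of 0.0687, and 0.06568 to 0.07523 with the saline arrays split. Of the calls 278 were higher under both oligos (48.1 for independent lists), 387 lower under both (45.3) and 6 opposite; simulated overlaps were 0. With the saline arrays split 91 to 108 were higher under both (8.258 to 14.81 for independent lists), 182 to 194 lower under both (11.26 to 15.1) and 0 to 7 opposite. Over all genes 73.5% had the same sign, within the simulated range of 34% to 89.8% (mean 66.3%), and 64.84% to 68% with the arrays split. Of the 665 genes called in the same direction by both, 583 were also called between the saline groups, among them Ramp3, Idi2 and Kcnab1, and these comparisons share the saline arrays.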

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

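The tests of a chip offset behind the HSALR saline against WT differences were chosen after the result was seen; the others in this part were planned or written down before. In groups of 4 arrays, a gap between an extreme array and the nearest other stands out where its share of the group's range (the ratio below) is above Dixon's 95% critical value, which chance gives for about 1 in 20 groups. Over 75 named genes and 5 array summaries in 4 groups, 19 of 320 values stood out, against 16 by chance.

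ASO 445236 replicate 2 had 4 of these, with a low raw 75th percentile of intensity (132.9 against 148.5 to 151.7, ratio 0.83) and high values of Flt1 (ratio 0.927), Idi2 (0.87) and Ramp3 (0.932). ASO 445236 replicate 1 was high in Ccl8 (0.831) and replicate 4 in Lgals3 (0.988). In WT, replicate 1 was low in Sln (6.79 against 9.30 to 9.77 on the log2 scale, ratio 0.845) and in Pi16 (0.959), and replicate 4 was low in Celf1 (0.868) and high in Kcnab1 (0.862). In HSALR saline, replicate 1 was high in Mup2 (8.69 against 4.64 to 5.09, ratio 0.889) and low in Pi16 (0.857), replicate 2 high in Nid1 (0.851), replicate 3 low in Ifi27l2a (0.908) and high in Ramp2 (0.888), and replicate 4 had fewer probes detected (0.854). In ASO 190401, replicate 1 was low in Celf2 (0.924), replicate 3 high in Rbfox1 (0.957) and replicate 4 low in Dmrtc1a (0.939).

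ASO 445236 and ASO 190401 differed in 266 genes by the limma test between these groups, among them Tmem45b, Wfdc17 and Socs2. The groups lay on different chips, so oligo and chip cannot be told apart here. Probes that the annotation leaves unnamed also changed: of 684 tested, 179 were called between HSALR saline and WT, 66 and 87 under ASO 445236 and ASO 190401 against saline, 54 and 53 under ASO 190401 and ASO 445236 against WT, and 18 between the oligos.

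Other splits of the 8 arrays of each comparison into 4 and 4 were counted, 35 per comparison with the real one. In each of the 6 comparisons 1 split, the real one, gave as many calls. That is a share of 0.0286, the smallest possible with 35 splits, which argues against chance but cannot exclude it. In the 4 comparisons across chips the real split also parts the chips. The real and highest other counts were 2374 and 64 for HSALR saline against WT, 1184 and 0 for ASO 445236 and 1376 and 1 for ASO 190401 against saline, 905 and 9 for ASO 190401 and 990 and 326 for ASO 445236 against WT, and 266 and 0 between the oligos. The split with 326 exchanges ASO 445236 replicate 1 with WT replicate 1, and the next gave 4. WT replicate 1 has the lowest array weight, 0.444, and the lowest value on component 2, -19.9; without it, ASO 445236 against WT called 1016 genes.

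HSALR saline and WT lay on different chips, as did ASO 190401 and HSALR saline, so an offset between chips could give differences there. A constant offset as the whole of the HSALR saline against WT differences would leave no return under ASO 445236, which shared a chip with saline; the lowest median return over 6 splits of the saline arrays was 42.22%, which argues against it. A constant offset as the whole of the return under ASO 190401 would leave that group as far from WT, on its own chip, as the return under ASO 445236 is large. The ratio of these reached 0.4853 at most over 36 splits of the saline and ASO 445236 arrays into pairs, with the genes picked on the other pairs, with a median of 0.2781, which argues against it too. An offset in a part of the genes, beside effects of genotype and oligo, stays open for the comparisons across chips.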

How the results depend on the processing

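Each alternative listed above was planned, and 0 were added later. Of the recomputed summary values 200 were the same and 31 moved. For counts, the same means within 1.5 times, and for the correlation of the oligo effects within its spread over arrays left out. For the return it means only that the sign and the fry call did not change, whatever the size. Requiring at least 2-fold left 323 genes for HSALR saline against WT, 165 and 123 for ASO 445236 and ASO 190401 against saline, 154 and 114 for ASO 190401 and ASO 445236 against WT, and 58 between the oligos. The test against 1.2-fold left 735, 258, 222, 194, 126 and 30 in the same order; both are stricter by construction. Median scaling called 1786 and 2234 genes for ASO 445236 and ASO 190401 against saline, and 2090 and 1619 for ASO 190401 and ASO 445236 against WT, with 85.6%, 86.8%, 86.5% and 89.9% of them higher, against 50.3%, 51.2%, 49.1% and 55.5%. Directions of small changes in these comparisons therefore rest on the scaling. The 8 arrays alone called 589 for ASO 190401 and 471 for ASO 445236 against WT, but 1325 and 1680 for ASO 445236 and ASO 190401 against saline, and array weights called 526 between the oligos; the cause was not tested.

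Leaving out 1 array gave 541 (without ASO 445236 replicate 3) to 1016 (without WT replicate 1) genes for ASO 445236 against WT and 110 to 276 (without ASO 445236 replicates 4 and 2) between the oligos. The ranges that stayed within 1.5 times were 1924 to 2517 for HSALR saline against WT, 854 to 1153 and 975 to 1325 for ASO 445236 and ASO 190401 against saline, and 627 to 948 for ASO 190401 against WT. Median return ran from 48.55% to 57.16% and from 53.73% to 59.67%. With the saline arrays split, the correlation of the oligo effects was 0.5378, 0.4625, 0.5363, 0.5313, 0.5699 and 0.5098, where no saline array was shared and each difference had 2 in place of 4; which of these lowered it was not tested. Camera with an estimated correlation kept 3 of 37 list calls. Fry, which does not compare a list with other genes, called 11, 5, 3, 13, 8 and 2 lists against 6, 5, 2, 10, 7 and 7 by camera, in the order of the comparisons above. The number of called members of a list moved by over 1.5 times with some array left out in 80 of the 124 pairs of list and comparison that had any, and reached 0 in 24. Of the list values 2004 were the same and 104 turned in the direction of the test, with no call before or after. Another 94 passed the threshold and 66 lost it. Of 399 called pairs of named gene and comparison 266 were called under every alternative, 22 lost the call only with an array left out and 111 under another setting. Srsf1 under ASO 445236 against WT turned from -0.242 to 0.007881 with median scaling; the cause was not tested. No paired analysis was made, since the labels carry no replicate numbers that would pair arrays. The replicate numbers used here follow the order of the arrays' positions on each chip. Probes near background limit the folds given as bounds.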

Other observations

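Tests of chip differences for genes far from WT and of single probes were chosen after the result was seen, as were the genes both oligos moved without a call between the saline groups. There were 82 such genes, 48 higher and 34 lower under both oligos. Most differed between HSALR saline and WT opposite to the oligo effect, short of the threshold, as Cyb5r1 did (-0.28, limma adjusted p = 0.0516). A few differed in the same direction, as Cavin3 did (-0.395, limma adjusted p = 0.0532). The comparisons share the saline arrays, so the set does not part oligo effects from a return toward WT. Ccl8, below background on every saline array, was at least 7.67-fold and at least 2.2-fold higher under ASO 445236 and ASO 190401. Wfdc17, above background on 2 of the 4 saline arrays, was higher by 3.80 ± 0.31 and 1.16 ± 0.31, and Herpud1, a gene of the endoplasmic reticulum stress response, by 0.30 ± 0.075 and 0.37 ± 0.075 (standard errors, 4 arrays per group). No group given an unrelated oligo was analysed here.

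Clock genes differed in HSALR saline from WT in 5 of 11 cases, 3 higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.532), with Per1 at 1.39 ± 0.19. Per1 was also higher than in WT under ASO 190401 (1.05 ± 0.19) and ASO 445236 (1.2 ± 0.19). The lists below were not called by camera in HSALR saline against WT, while fry called actins lower (adjusted p = 0.000125) and oxidative phosphorylation lower (0.000437). Camera adjusted p was 0.532 for fast fibre, 0.112 for actins, 0.954 for RNase H (2 measured, 0 called), 0.29 for oxidative phosphorylation, 0.536 for glycolysis and glycogen, 0.327 for endothelial cells and 0.986 for smooth muscle. It was 0.382 for erythroid cells, 0.954 for nerve and Schwann cells and for satellite cells, 0.935 for heat shock, 0.954 for atrophy and proteasome, 0.672 for the unfolded protein response and 0.779 for ribosomal proteins. Of the 12 lymphocyte markers 0 were measured.

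Myeloid markers were higher under ASO 445236 than under saline. A lower share of muscle RNA, with the other cell types in unchanged proportions, would raise the markers of them all alike. The myeloid list's mean minus that of the other types was 1.07 higher under ASO 445236 (exact permutation p = 0.02857, the smallest possible). The myeloid list had the highest median of these lists on the same arrays, so this p is not free of that selection. Per group the difference of means was -1.09 ± 0.309 in HSALR saline, -0.0195 ± 0.381 under ASO 445236 and -0.38 ± 0.156 under ASO 190401 (SD, n = 4 each). In WT it was -0.998 ± 0.393 (SD, n = 4). The rise under ASO 190401 was not tested. Under ASO 445236 medians did not rise alike, at 0.98 for myeloid, 0.668 for adipocyte, 0.417 for erythroid and 0.197 for fibroblast markers. They were -0.0629 for nerve, -0.349 for smooth muscle and -0.52 for endothelial markers, which argues against a lower share of muscle RNA that raises every other cell type alike. The test cannot decide on a change in the pieces that raises only some cell types. Of the 15 measured markers 10 were called, among them the 5 brightest, Lyz1 (1.68 ± 0.25), Laptm5 (1.68 ± 0.23), Cd74 (1.30 ± 0.32), Lgals3 (1.49 ± 0.18) and Lyz2 (1.93 ± 0.33), and 11 were above background on all saline arrays and 13 on all WT arrays, and 0 are in another list. More myeloid cells and more RNA per myeloid cell stay open as hypotheses, and no cells were counted in the data used here.

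In all 3 HSALR groups 13 genes differed over 4-fold from WT, 11 higher (among them Pcdhb12, Cacna2d3, Atrip, Chic2 and Sln) and 2 lower (Dkk3 and Sytl2). Genes picked for such differences of HSALR saline and ASO 445236 from 2 WT arrays (13 to 17 genes, with at least 12 of the 13) kept a median of 0.9579 to 1.048 of them between ASO 190401 and the other 2 WT arrays, within 1 chip, over 6 splits, which argues against a chip difference. Genes with no probe above background in WT cover 2 of the 11, which argues against genes off in WT as the rule for the set, and 0 pairs lay within 10 Mb (100% of 10000 random sets had as many, with a mean of 0.82) while 4 pairs shared a chromosome (61.6% had as many), the 13 genes lying on 9, which argues against 1 linked region for the set but not against regions that hold single genes. For Pdlim2, Tsr2 and Vmp1 the other probes moved by at most 0.0916 of the leading probe's difference, so a signal of 1 probe, from a transcript form or another RNA, is a candidate explanation, while for Chic2 and Dkk3 the lowest ratio was 0.827, which argues against it. Genetic differences besides the transgene between the HSALR line and WT mice, both described as FVB/n, stay open. So does an effect of the transgene that these oligos did not or only partly reverse: Pcdhb12, Dmrtc1a and Pdlim2 fell under both oligos and Tsr2 and Slc25a33 under ASO 445236, while Slc25a33 under ASO 190401 (adjusted p = 0.037; up to 0.0903 without any 1 saline array or ASO 190401 replicate 2, 3 or 4) and Vmp1 under ASO 445236 (0.022; up to 0.0715 without ASO 445236 replicate 1 or 4 or saline replicate 3 or 4) lost their calls.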
